A study of Homo sapiens with 24 samples.

How the data were processed

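Gene expression was measured on 24 one-colour (Cy3) Agilent 4x44K whole human genome arrays, each of which held 45015 spots. The samples were cultures of HepG2, a human hepatocellular carcinoma line. Per the labels, 3 test centres each bought the line, kept a cell bank of their own and exposed triplicate wells to benzo[a]pyrene (B[a]P) or to its solvent dimethyl sulfoxide (DMSO, 0.5%) for 24 h. Per the labels' protocols, the stock solutions were made at 1 centre and sent to the others. The dose is given as 3 µM in the treatment protocol and as 3 mM in the series design text; the printed values do not depend on which is right. The labels call the replicates biological replicates, and the passage and cell bank of single replicates are not given in the sources used here. P-values therefore measure the spread between these cultures.

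Per the labels' protocols, total RNA was extracted with Trizol and purified on columns, and Cy3-labelled cRNA was made with a one-colour kit. The deposited values are intensities on a linear scale. Per the file headers, Agilent Feature Extraction subtracted the background, removed the spatial trend within each array and wrote the processed signal of each spot, with no scaling between arrays. Per the labels, the version was 10.5.1.1 for all samples. Per the file headers, it was 9.5.1.1 in centre 1 and 10.5.1.1 in centres 2 and 3, and the scanner model differed in the same way. The deposited value table of the series held the same processed signals: none of 1080360 values differed from the scanner file of its array by more than a relative tolerance of 1e-06. Its column medians ran from 23.1 to 111.5. Its scale is therefore linear and uncentred, and it has no direction, being a level and no ratio; as an alternative to the scanner files it was void.

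The scanner files of all 24 arrays were read, and control spots (leaving 43376 spots) and spots marked as outliers were left out; saturated spots were kept. Replicate spots of a probe were averaged, which gave 41000 probes. The log2 processed signal of each array was expressed relative to the 75th percentile of the processed signal over its non-control probes. Arrays of the same RNA were averaged, which turned 24 arrays into 18 biological replicates in 6 groups of 3; 105 values were missing after the outlier spots were removed. A probe was kept where Feature Extraction called it well above background in all 3 replicates of at least 1 group, which left 29975 probes, and each gene was represented by its brightest probe, which left 22024 genes. Probe positions were taken from the file headers and annotation columns, which name build hg18. The place of a probe within its exon or untranslated region was not analysed here.

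Gene names came from the array annotation. The accession or symbol of a probe was updated through a RefSeq gene table of assembly GRCh38, used for names alone: 23958 probes matched by accession, 2755 by symbol and 1032 by an older symbol, 27745 in all with 17843 distinct names. The other 13255 probes kept the name in the array design. Probes of near-identical copies, such as the MT1 metallothioneins, the alpha globins HBA1 and HBA2, the AKR1C reductases and clustered histones, can bind more than 1 transcript, and UGT1A6 shares its last exons with other UGT1A forms; their values are uncertain as to the copy.

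Tests were run in R 4.3.3 with limma 3.58.1 (lmFit and eBayes, two-sided) and version 1.17.8 of data.table; figures were drawn with Python 3.11.15, numpy 2.4.6, pandas 2.3.3 and matplotlib 3.10.9. P-values were adjusted by the Benjamini-Hochberg method, and genes with an adjusted p under 0.05 were called. B[a]P was compared with DMSO within each centre on its 6 replicates. The combined effect was the mean of the 3 centre effects in a fit of all 18 replicates. Centre dependence of the effect, and the DMSO level, were tested with moderated F-tests in the same fit, followed by pairwise differences. Gene lists were tested with camera at a preset inter-gene correlation of 0.01 and again with an estimated correlation; list tests in single centres used the centre's contrast in the fit of all 18 replicates unless stated otherwise. Camera left out genes with missing values. In the fit of all 18 replicates it used 24 of 28 hepatocyte markers, 27 of 28 NRF2 targets and 21 of 22 ATF4 and unfolded protein response genes. There were 19 lists: targets of the aryl hydrocarbon receptor (AhR), p53 and NRF2, nucleotide excision repair, homologous recombination and Fanconi anaemia, G1/S and DNA replication, G2/M and mitosis, histones, hepatocyte markers, cholesterol synthesis and uptake, fatty acid oxidation, drug metabolism under PXR and CAR, ATF4 and the unfolded protein response, inflammation, metallothioneins, and markers of fibroblasts, blood and immune cells, endothelium, and squamous or lung epithelium.

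The lists, the tests and the rule for naming genes were fixed before the data were examined. The rule named CYP1A1, CYP1B1 and CDKN1A in any case; up to 10 largest rises and 10 largest falls among genes called in each centre with the same sign; up to 4 members of each list with the smallest adjusted p; the 5 largest rises and 5 largest falls called in each centre; the 10 smallest p-values of centre dependence; and the 10 largest ranges of DMSO means. It named 114 genes. Because the overlap of the 3 centres held a single gene, the largest changes among genes called in each centre with the spread taken from all 18 replicates were added after values had been seen, which named 12 further genes. Some of the genes named by the rule, and some members of small list counts, are not reported here.

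Where a gene's probe was not well above background on any array of 1 group, the change is given as "at least" a fold, the mean of the brighter group over a bound for the dimmer one. The bound was, per array, the higher of the probe's own value and the lowest value among probes well above background. Such genes also have a fitted change, which is no bound.

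The steps were tested on simulated data with 200 changed genes among 21931, with each gene's spread taken from the replicates. A change of 1 on the log2 scale was recovered for 27% of changed genes in centre 1, 5% in centre 2, 90% in centre 3 and 92% in the combined fit. A change of 2 was recovered for 92%, 83%, 99% and 100%. The simulated noise was independent between genes, so a shift of many genes together in a replicate was left out. These shares and the false calls hold for such noise alone: in the data of centre 1 neither CYP1A1 nor CDKN1A passed. False calls were 8 of 127, 3 of 91 and 17 of 206 in the single centres. They were 31 of 223 in the combined fit, 24 of 137 for centre dependence and 44 of 204 for DMSO levels, which is above the nominal 5%. With the spread of each centre taken on its own they were 39 of 234, 27 of 130 and 42 of 200. With an equal spread in all centres, false calls were 12 of 209, 5 of 98 and 10 of 170. The number of arrays limits the precision of every value. Alternatives covered the background correction, the scaling between arrays, the filter on dim probes, the choice among a gene's probes, technical arrays, the slide and the replicate number as blocks, the threshold, the spread, and omission of each replicate and each centre. The normexp background correction also added an offset of 50 to the corrected signal, so its values hold the effect of both.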

Results

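Expression profiles of HepG2 liver carcinoma cells were obtained after 24 h with benzo[a]pyrene (B[a]P), a polycyclic aromatic hydrocarbon that cells oxidise to DNA-reactive products, or with the solvent DMSO. The study asked how far toxicogenomic results repeat within a laboratory and between laboratories, and 3 test centres followed 1 protocol. Each centre provided 3 biological replicates of B[a]P and 3 of DMSO, so that 6 groups of 3 made 18 RNAs. Of these, 4 RNAs were hybridised more than once: B[a]P replicate 1 of centre 1 and B[a]P replicate 2 of centre 3 on 3 arrays each, and replicate 3 of both treatments of centre 2 on 2 arrays each. The 75th percentile of the processed signal was 628 to 1218 on the arrays of centre 1, 316 to 1102 in centre 2 and 652 to 1167 in centre 3. Between 61.9% and 77.2% of probes were well above background. No 2 RNAs held identical values, and the highest correlation among the 153 pairs was 0.997. Each slide belonged to a single centre. In centre 1 and centre 2 both treatments shared a slide; in centre 3 the slide that held DMSO carried B[a]P replicate 1, and the other slide held B[a]P alone. The 2 slides of centre 2 were scanned 77 days apart, and those of centres 1 and 3 on the same day.

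CYP1A1, the monooxygenase that oxidises B[a]P and the classical target of the aryl hydrocarbon receptor (AhR), rose 33.2-fold (log2 change 5.05 ± 0.29, SE, n = 18; limma adjusted p = 1.86e-07). CDKN1A, which encodes the p53-induced cell cycle inhibitor p21, rose 4.11-fold (2.04 ± 0.18; adjusted p = 2.25e-06). The metallothionein MT1X, a small cysteine-rich metal-binding protein, rose 5.68-fold (2.51 ± 0.26). MVD, the mevalonate decarboxylase of cholesterol synthesis, was 3.38-fold lower with B[a]P (-1.76 ± 0.16). The probe of CYP1A1 lies on chromosome 15 at 72799615 to 72799674 (hg18), and that of CDKN1A on chromosome 6 at 36762684 to 36762743.

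Relative to the array's 75th percentile, the log2 level of CYP1A1 was 2.34 ± 1.35 with B[a]P and -2.45 ± 0.71 with DMSO in centre 1 (SD, n = 3). CYP1A1 measured 0.97 ± 0.20 and -3.22 ± 0.55 in centre 2, and 4.31 ± 0.29 and -1.87 ± 0.30 in centre 3. Every B[a]P replicate lay above every DMSO replicate of its centre for CYP1A1, CDKN1A and MT1X. CYP1B1, a related monooxygenase that also oxidises hydrocarbons (chromosome 2, 38148948 to 38149007), rose with a fitted change of 1.03 ± 0.28 (adjusted p = 0.00953). Its probe was well above background in B[a]P of centre 3 alone, where it rose at least 2.29-fold, and its combined change turned to -0.34 under normexp background correction and did not pass without centre 3 (0.81; adjusted p = 0.135).

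**Figure D1:**
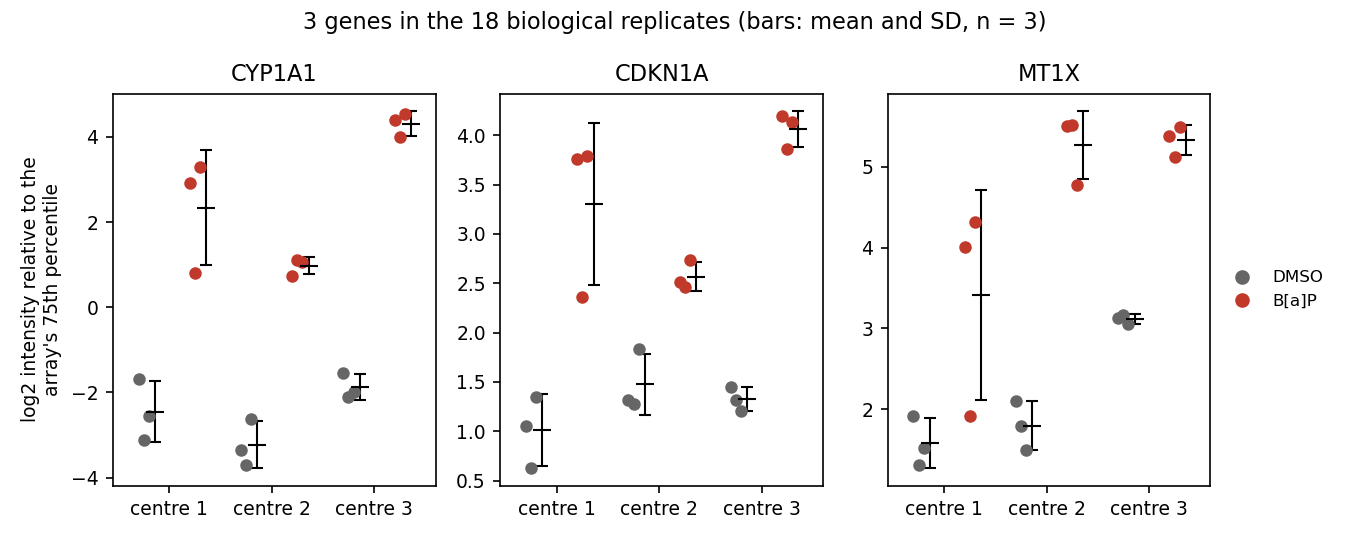
Log2 signal relative to the array's 75th percentile of CYP1A1, CDKN1A and MT1X in DMSO and B[a]P cultures of each centre; points are biological replicates, and bars give the mean and SD (n = 3). CYP1A1 spanned 0.74 to 4.55 in the B[a]P cultures and -3.70 to -1.53 in the DMSO cultures.

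In all, 7924 of 22024 genes (36.0%) differed between B[a]P and DMSO in the combined fit, of which 3624 rose and 4300 fell. The majority turned under median scaling (4183 rose, 3453 fell), with the trend of probe GC content removed (4088 and 3875), at a minimum change of 2-fold (494 and 471 of 965) and under normexp background correction (1269 and 1263 of 2532). Without centre 3 the count was 4413. Of the 19 gene lists, 7 shifted up and 3 down in camera at the preset correlation. With an estimated correlation none of the 10 passed, and their smallest adjusted p was 0.0836.

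AhR targets rose as a group: 9 of 16 members rose, 1 fell and 6 did not pass (10 rose and 1 fell adjusted over the list alone; camera adjusted p = 7.25e-05; adjusted p = 0.0836 with an estimated correlation). Beside CYP1A1 and CYP1B1 these included the aldehyde dehydrogenase ALDH3A1 (2.71 ± 0.19), the glucuronosyltransferase UGT1A6 (0.97 ± 0.09) and the efflux pump ABCG2 (0.94 ± 0.11). The member that fell was the amino acid transporter SLC7A5 (-0.33 ± 0.09), which, like other members named beside counts of 5 or fewer, was chosen after its value was seen. Among p53 targets, 29 of 36 rose and 2 fell, over all genes and adjusted over the list alone (camera adjusted p = 5.16e-15; adjusted p = 0.0836 with an estimated correlation). The growth suppressor BTG2 rose by 1.13 ± 0.08, the death receptor FAS by 1.51 ± 0.13, the ribonucleotide reductase subunit RRM2B by 0.94 ± 0.09 and the damage sensor DDB2 by 0.79 ± 0.10. The decoy receptor TNFRSF10C was among those that fell (-0.31 ± 0.10).

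NRF2 targets, which include detoxifying and antioxidant enzymes, rose in 17 of 28 members, and 1 fell, with equal counts adjusted over the list alone (camera adjusted p = 4.79e-07; adjusted p = 0.102 with an estimated correlation). The aldo-keto reductases AKR1B10 and AKR1C1 rose by 2.07 ± 0.18 and 1.07 ± 0.09, the export pump ABCC2 by 0.86 ± 0.08 and sulfiredoxin SRXN1 by 1.00 ± 0.12. Of 10 genes in the metallothionein list, 9 rose (9 adjusted over the list alone; camera adjusted p = 1.87e-08; adjusted p = 0.131 with an estimated correlation), among them MT1G (2.43 ± 0.24), MT1H (2.55 ± 0.25) and MT1B (2.45 ± 0.25). Of 14 inflammatory and acute phase genes, 8 rose and none fell (8 adjusted over the list alone; camera adjusted p = 4.78e-04; adjusted p = 0.375 with an estimated correlation). Examples were the cytokine LIF (1.61 ± 0.20), the NF-kappaB subunit RELB (1.25 ± 0.19), the adhesion molecule ICAM1 (0.65 ± 0.12) and the apoptosis inhibitor BIRC3 (1.75 ± 0.33).

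Histone genes shifted up (7 of 30 rose, 1 fell, and likewise adjusted over the list alone; camera adjusted p = 0.00947; adjusted p = 0.548 with an estimated correlation). H1-2, H2AC18 and H2AC8 rose by 0.88 ± 0.10, 0.85 ± 0.14 and 0.57 ± 0.12, whereas the variant histone H2AX fell (-0.44 ± 0.09). Without centre 2 the shift of the histones was lost (adjusted p = 0.85), as it was without DMSO replicate 3 of centre 2 (adjusted p = 0.053). Blood and immune cell markers also shifted up, with 4 of 9 rising and none falling (4 rose and 1 fell adjusted over the list alone; camera adjusted p = 0.0186; adjusted p = 0.304 with an estimated correlation). These were the T cell receptor component CD3D (3.14 ± 0.24), the alpha globin HBA1 (0.61 ± 0.12), the monocyte receptor CD14 (0.72 ± 0.15) and the macrophage protein CD68 (0.28 ± 0.09). PTPRC, MS4A1 and HBB, markers of leukocytes, B cells and red cells, did not pass the filter on signal.

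Genes of cholesterol synthesis and uptake fell together: 20 of 24 fell and none rose (21 fell adjusted over the list alone; camera adjusted p = 4.32e-11; adjusted p = 0.0836 with an estimated correlation). Beside MVD these included lanosterol synthase LSS (-1.09 ± 0.12) and the last-step reductase DHCR7 (-0.91 ± 0.09). G1/S and DNA replication genes fell in 19 of 35 members, none rose, and the count adjusted over the list alone was 19 (camera adjusted p = 7.25e-05; adjusted p = 0.405 with an estimated correlation). Among them were the replicative helicase subunits MCM5 (-0.82 ± 0.09), MCM2 (-0.74 ± 0.09) and MCM6 (-0.91 ± 0.12) and the flap endonuclease FEN1 (-0.88 ± 0.11). Hepatocyte markers shifted down, with 10 of 28 falling and 1 rising, also adjusted over the list alone (camera on 24 members, adjusted p = 0.0184; adjusted p = 0.453 with an estimated correlation). Those that fell included the liver transcription factor CEBPA (-1.31 ± 0.09), the urea cycle enzyme CPS1 (-1.05 ± 0.11), fibrinogen chain FGA (-0.79 ± 0.11) and haptoglobin HP (-0.46 ± 0.10); the member that rose was the aminotransferase TAT (0.72 ± 0.25). The shifts of the G1/S, hepatocyte and blood marker lists were lost without centre 3, and those of the hepatocyte and blood marker lists also without centre 1 and under normexp background correction. Blood markers lost theirs as well among genes detected in all 18 replicates (adjusted p = 0.133).

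Other lists did not shift in the combined fit as first tested. Mitotic genes had 12 of 34 members lower and 1, NEK2 (0.22 ± 0.08), higher, with equal counts adjusted over the list alone (camera adjusted p = 0.138). Lower were the mitotic activator CDC20 (-0.60 ± 0.08), the kinase AURKB (-0.62 ± 0.09), the proliferation antigen MKI67 (-0.95 ± 0.16) and the phosphatase CDC25B (-0.46 ± 0.08). By centre, mitotic genes shifted down in centre 3 (camera adjusted p = 1.36e-04, and 0.334 with an estimated correlation). They also did in centre 1 (0.0183 and 0.458), though not on its 6 replicates alone (0.0626), and did not shift in centre 2 (0.493). The mitotic list did shift down without centre 2, under quantile normalization (adjusted p = 0.0127), with the trend of probe GC content removed (0.0349) and without B[a]P replicate 2 of centre 1 (0.0322), each at the preset correlation (adjusted p = 0.705 with an estimated correlation for the list as first tested). In nucleotide excision repair 7 of 26 rose and 5 fell (8 and 5 adjusted over the list alone; camera adjusted p = 0.377). DDB2, named above among the p53 targets, also belongs to this list and rose by 0.79 ± 0.10. The transcription-coupled repair factor ERCC6 rose by 0.49 ± 0.10 and the TFIIH subunit GTF2H5 by 0.41 ± 0.08, while the DNA ligase LIG3 fell (-0.57 ± 0.09). Another probe of LIG3 was called the opposite way. In homologous recombination and Fanconi anaemia 2 of 27 rose, RAD51C (0.38 ± 0.09) and RAD50 (0.34 ± 0.13), and 2 fell, XRCC3 (-0.48 ± 0.17) and FANCG (-0.26 ± 0.10). Another probe of RAD50 was lower and did not pass (adjusted p = 0.0722). Adjusted over the list alone 1 rose and none fell (camera adjusted p = 0.952), and the median change of the list was 0.02 against a mean of -0.02. The centres differed, with medians of -0.09, 0.28 and -0.30 in centres 1, 2 and 3. In centre 3 the recombination list shifted down, with 8 members falling and 1 rising (camera adjusted p = 0.013, and 0.362 with an estimated correlation). Centre 2 did not pass (0.0567).

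**Figure D2:**
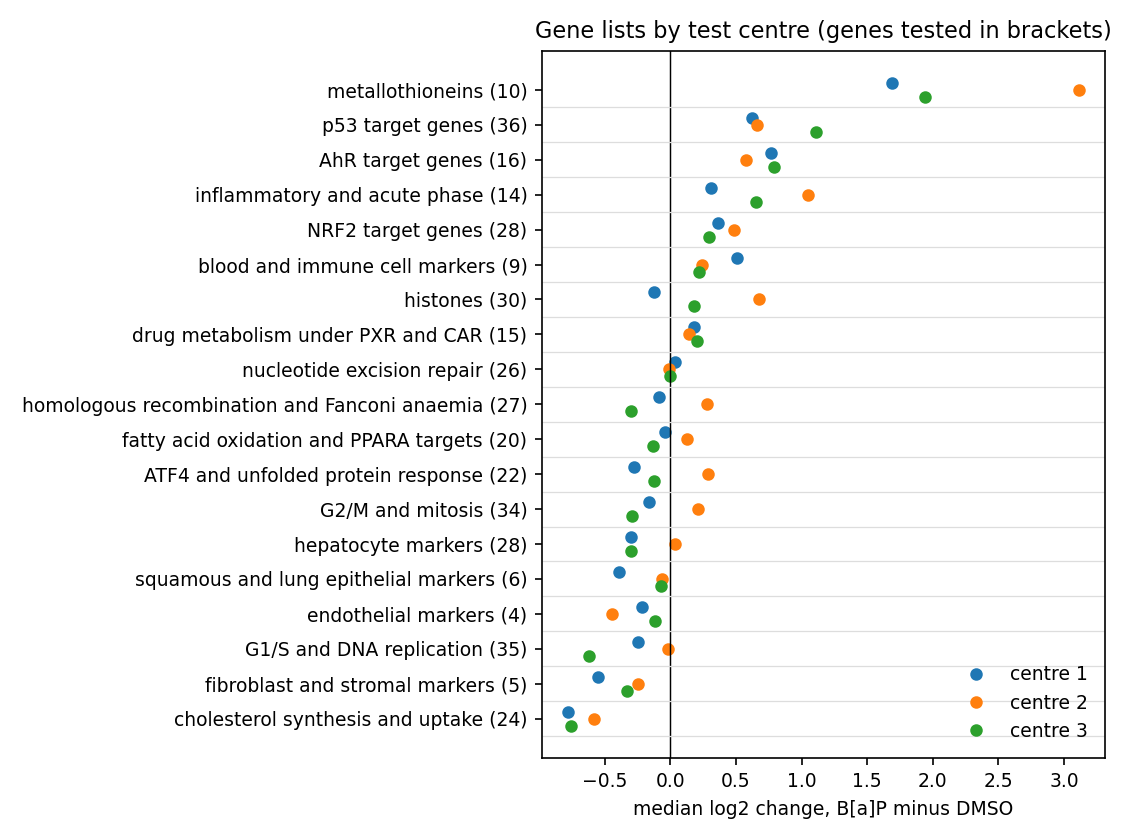
Median log2 change (B[a]P minus DMSO) of each of the 19 gene lists, with 1 point per centre. The metallothionein medians were 1.69, 3.12 and 1.94 in centres 1, 2 and 3, and the histone medians -0.13, 0.68 and 0.18.

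Within centre 1, CYP1A1 measured 27.6-fold higher with B[a]P (4.79 ± 0.68, SE, n = 6), but it did not pass the test there (adjusted p = 0.129), nor did CDKN1A (2.29 ± 0.42; adjusted p = 0.15). The single gene called in centre 1 was AKAP14, an anchoring protein of protein kinase A (chromosome X, 118937903 to 118938506), with a fitted change of -2.42 ± 0.15 (adjusted p = 0.0238). It was at least 1.5-fold lower with B[a]P, from a level above background on 2 of 3 DMSO arrays, and lost its call under quantile normalization (adjusted p = 0.102). In limma 1 of 22024 genes therefore passed, while 3415 had an unadjusted p under 0.05. The list of p53 targets had a median change of 0.62 in this centre (18 rose and 1 fell adjusted over the list alone), and cholesterol genes of -0.78 (19 fell adjusted over the list alone). The number of calls rested on B[a]P replicate 2, without which 686 genes were called (330 rose, 356 fell), and was 0 without any 1 of the other 5 replicates, with the slide as a block (3114 at an unadjusted p under 0.05) and within the slide that held 2 B[a]P and 2 DMSO replicates (884). With the spread taken from all 18 replicates it was 654.

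In centre 2, CYP1A1 rose 18.3-fold (4.20 ± 0.30; adjusted p = 0.00441), and the metallothioneins MT1H, MT1X and MT1A rose by 3.53 ± 0.33, 3.47 ± 0.28 and 3.43 ± 0.30. The pseudogene ANKRD30BP2 measured at least 4.41-fold higher, but its change turned to -0.17 under normexp background correction. The largest falls were those of SUN2, a protein of the inner nuclear membrane (-4.00 ± 0.35), the ethanolamine kinase ETNK2 (-3.29 ± 0.29), CLUH, which binds mRNAs of mitochondrial proteins (-3.15 ± 0.19), the adaptor SH2B1 (-2.89 ± 0.32) and the protocadherin PCDHB9, which was at least 1.75-fold lower. Of 22024 genes, 2854 were called, 1195 higher and 1659 lower; the majority turned under median scaling (1435 and 1369) and with the spread from all 18 replicates (3891 and 3283). Omission of B[a]P replicate 3 gave 5098, and that of B[a]P replicates 1 or 2 or DMSO replicates 1 or 2 gave 406, 323, 742 and 530. With the slide as a block there were 5215 calls, within the slide of replicates 1 and 2 9052, and under normexp background correction 0 (1864 at an unadjusted p under 0.05).

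In centre 3, CYP1A1 rose 72.6-fold (6.18 ± 0.20; adjusted p = 7.55e-05). The lipid transporter ABCA12 rose at least 13.7-fold, the neuronal RNA-binding protein ELAVL3 at least 8.82-fold and the steroid dehydrogenase HSD3B1 at least 8.61-fold, and the myeloid receptor TREM2 by 5.25 ± 0.32. Among the largest falls were those of LRMDA (-3.51 ± 0.19), the adhesion molecule SDK1 (-3.41 ± 0.24), the mitochondrial carrier SLC25A21, which was at least 4.73-fold lower, and the proteoglycan GPC6 (-3.10 ± 0.18). Replication genes were lower in 23 of 35 members here, with a median of -0.62. In all 6473 genes were called, 2873 higher and 3600 lower. The majority turned under median scaling (3140 and 2816), normexp background correction (1785 and 1483), a minimum of 2-fold (817 and 759) and an adjusted p under 0.01 (1539 and 1465). It also turned with the slide as a block (1329 and 1119 of 2448), and within the slide that held 1 B[a]P and 3 DMSO replicates (1445 and 1322 of 2767), where the lone B[a]P replicate was taken to vary like the other group. Without DMSO replicate 2 the count was 3557.

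Tested on the 6 replicates of each centre alone, camera called 10 lists in centre 1, 7 in centre 2 and 11 in centre 3 at the preset correlation. With an estimated correlation, in the fit of all 18 replicates, 5 passed in centre 1 (AhR, p53 and NRF2 targets and cholesterol genes, adjusted p = 0.0247 each, and blood markers, 0.0451), none in centre 2 (smallest adjusted p = 0.478) and 1 in centre 3 (p53 targets, 0.0359). With the slide as a block 9, 7 and 11 of the lists called at the preset correlation were called again, and within the slide that held both treatments 9, 7 and 11; all kept their direction.

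The medians of the AhR, p53, metallothionein and cholesterol lists had the same sign in every centre, but a single gene passed the threshold in all of them. AKAP14 was the single gene called in each centre with the same sign (0.0123 were expected of independent lists), at least 1.27-fold lower in centre 2, and below background in both groups of centre 3. No gene rose in all 3 per-centre tests by limma, in which 3415, 6858 and 9529 genes had an unadjusted p under 0.05. Centres 2 and 3 shared 589 genes that rose (155.9 expected of independent lists) and 579 that fell (271.2 expected), and 106 were called in opposite directions (411.7 expected). Of the 1168 genes called in the same direction in both, 1143 (97.9%) had that sign in centre 1. Without B[a]P replicate 2 of centre 1, the shared genes numbered 231. With the spread from all 18 replicates, the lists of the 3 centres shared 1 spread per gene and were not independent, so the expected counts can be too low. In that setting 217 genes rose in every centre (4.25 expected of independent lists) and 148 fell (3.72 expected).

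Among these, chosen after the values had been seen, the largest combined rises were those of CYP1A1, the melanosome adaptor MLPH (4.06 ± 0.33), the egg coat protein ZP1 (3.37 ± 0.21), CD3D, TMEM92 (3.12 ± 0.35), LRRC25 (3.08 ± 0.26), the transglutaminase TGM5 (3.03 ± 0.27), the antisense RNA DIO3OS (2.79 ± 0.19), ANKRD30BP2 (2.73 ± 0.30) and ALDH3A1. Several were dim with DMSO: ZP1 rose at least 8.98-fold in centre 3 and TMEM92 measured at least 5.23-fold higher in centre 1, and DIO3OS at least 3.05- and 4.30-fold in centres 2 and 3. Under normexp background correction the combined changes of DIO3OS and ANKRD30BP2 turned to -0.02 and -0.06, and a dimmer probe of DIO3OS showed no rise (-0.05 ± 0.24; adjusted p = 0.882). Among the largest falls were those of the kinesin KIF26B (-2.82 ± 0.18), the melanosomal transporter OCA2 (-2.80 ± 0.27), SDK1 (-2.47 ± 0.20), SLC25A21 (-2.34 ± 0.21), the adhesion receptor ADGRV1 (-2.31 ± 0.23), LRMDA (-2.29 ± 0.21), the urea cycle enzyme OTC (-2.24 ± 0.31), NKAIN2 (-2.18 ± 0.22) and the tight junction protein TJP3 (-2.13 ± 0.25). Of these KIF26B, OCA2, SLC25A21, OTC and NKAIN2 were not well above background with B[a]P in at least 1 centre, so that their fitted changes are no measured size; KIF26B was at least 1.80-fold lower in centre 2 and at least 2.19-fold lower in centre 3. Of the dimmer probes of SDK1, 1 fell (-1.68) and 1 did not pass (-0.17).

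Across genes, which are no independent replicates, the log2 changes correlated with r = 0.41 between centres 1 and 2 (rho = 0.375), 0.693 between centres 1 and 3 (rho = 0.615) and 0.45 between centres 2 and 3 (rho = 0.42). The centres shared no control arrays.

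**Figure D3:**
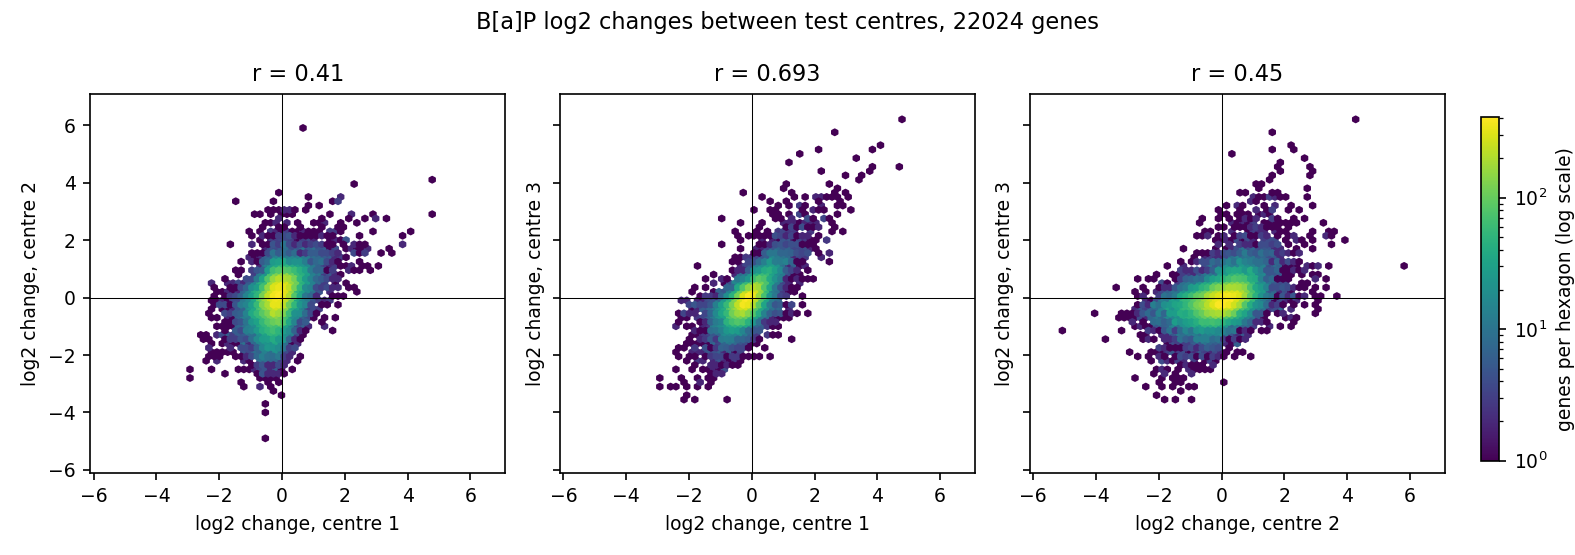
Log2 change (B[a]P minus DMSO) of 22024 genes in 1 centre against another, for each pair of centres; the shade gives the number of genes per hexagon on a log scale. The correlation across genes was 0.41 for centres 1 and 2, 0.693 for centres 1 and 3, and 0.45 for centres 2 and 3.

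The size of the B[a]P effect depended on the centre for some of its best known targets. CDKN1A rose 6.67-fold in centre 3 and 2.13-fold in centre 2 (difference of the log2 changes -1.65, centre 2 minus centre 3; adjusted p = 0.0226), and ALDH3A1 differed likewise (-1.92; adjusted p = 0.0138). By the moderated F-test of centre dependence, CDKN1A passed just under the threshold (adjusted p = 0.0477) and ALDH3A1 passed as well (0.0237). CYP1A1 passed no test of centre dependence (adjusted p = 0.164). The genes with the smallest p of centre dependence were changed in centre 2 above all. C2orf68 fell there (-2.63 ± 0.19) and rose in centre 3 (0.58 ± 0.12), as did TINAGL1, an extracellular matrix protein (-2.12 ± 0.20 and 0.60 ± 0.14), and DBNDD1 (-2.26 ± 0.17 and 0.66 ± 0.14).

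The forkhead factor FOXN2 and the signalling adaptor BCL10 rose by 2.44 ± 0.21 and 2.18 ± 0.16 in centre 2. Falls in centre 2 were those of serine dehydratase SDS (-2.54 ± 0.19), the chromatin remodeller SRCAP (-2.44 ± 0.21), the clathrin adaptor subunit AP1B1 (-2.07 ± 0.19), the nucleolar protein SURF6 (-2.74 ± 0.18) and the zinc finger protein ZNF76 (-2.56 ± 0.20). The changes of these 7 genes in centre 1 lay between -0.37 and 0.07. With C2orf68, TINAGL1 and DBNDD1, the adjusted p of centre dependence ran from 5.58e-06 to 6.81e-05.

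By the moderated F-test, 2339 genes depended on the centre. Pairwise, 2224 differed between centres 1 and 2, 2786 between centres 2 and 3, and 2 between centres 1 and 3 (1400 at an unadjusted p under 0.05). Without centre 2 no gene passed (1927 at an unadjusted p under 0.05), without centre 3 821 did, and under normexp background correction 147. Omission of B[a]P replicate 3, 1 or 2 of centre 2 gave 3733, 1544 and 1370.

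The p53 targets moved further up in centre 3, with a median of 1.11, than in centre 1 (0.62; camera adjusted p of the difference 7.73e-07; p = 0.0519 with an estimated correlation) or centre 2 (0.66; adjusted p = 3.11e-05; p = 0.088 with an estimated correlation). The B[a]P change of the replication genes was lower in centre 3 than in centres 1 and 2 (adjusted p = 5.95e-10 and 4.83e-05; p = 0.0385 and 0.142 with an estimated correlation). The B[a]P change of the histones was higher in centre 2 than in centre 1 (adjusted p = 7.73e-07; p = 0.0698 with an estimated correlation) or centre 3 (0.00101; p = 0.191 with an estimated correlation).

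DMSO cultures also differed between centres, and the largest differences were those of single probes. TNRC18, a chromatin protein, had a log2 level of 4.42 in centre 1, -3.22 in centre 2 and 4.75 in centre 3, where the mean of centre 2 rests on 1 replicate. The diacylglycerol kinase DGKH measured -3.38, -6.01 and 0.83, the metallothionein MT1M -4.49, -6.89 and -0.06, and the poly(A)-binding protein PABPC3 -2.67, -5.33 and 1.43 in centres 1, 2 and 3. The signal recognition particle pseudogene SRP14P1 measured -0.81, -5.31 and 2.13, and CTAGE6 -2.53, -6.60 and 0.30. The methyltransferase CARNMT1, the RNA-binding protein ZCRB1, the F-box protein FBXO10 and the annexin pseudogene ANXA2P3 were not well above background in centre 2 and were highest in centre 3, at -1.56, -1.15, -2.36 and -2.14. The adjusted p of these 10 genes ran from 6.93e-13 to 6.42e-09.

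The moderated F-test called 12331 genes in DMSO, and 10343 with the slide as a random block; the count under normexp background correction was 2033. Centre 1 differed from centre 2 in 6372 genes (2315 higher, 4057 lower in centre 1) and from centre 3 in 8870 (3036 higher, 5834 lower), and centre 2 differed from centre 3 in 9102 (4888 higher, 4214 lower in centre 2). Each centre had its own slides and cell bank, so that these cannot be told apart from one another.

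**Figure D4:**
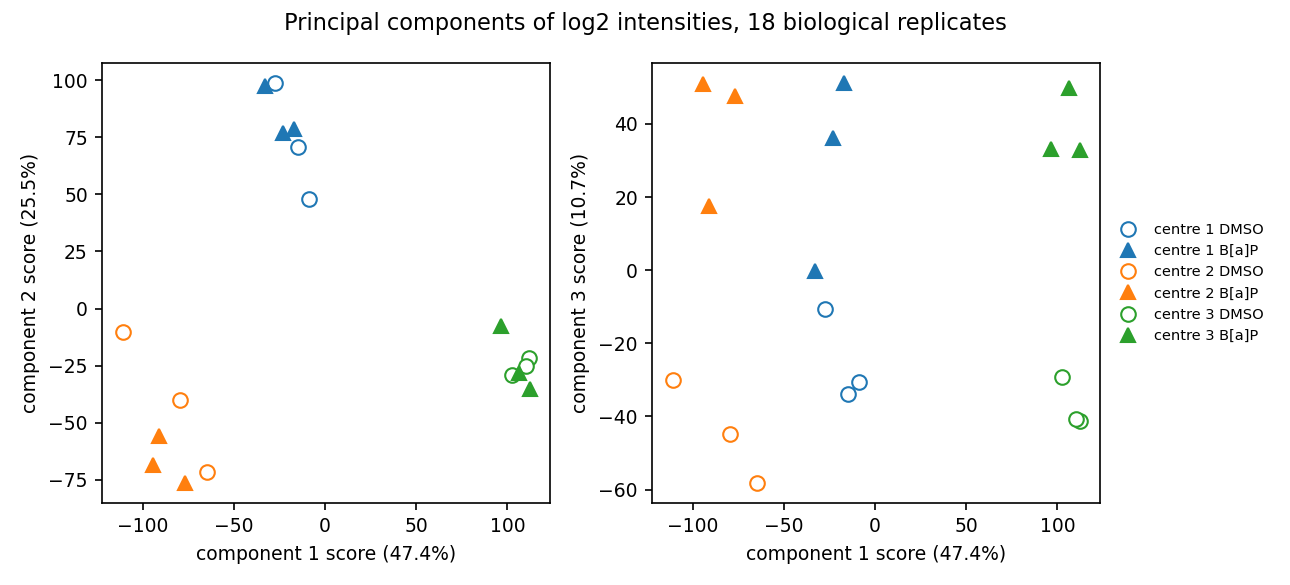
Scores of the 18 replicates on the first 3 principal components of 21931 genes, which held 47.4%, 25.5% and 10.7% of the variance. Component 1 placed centre 3 from 96.6 to 112.3 and centre 2 from -110.9 to -64.6, and component 3 placed B[a]P replicates at -0.15 or above and DMSO replicates at -10.6 or below.

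Of the sum of squares over genes, 70.3% lay between centres, 9.39% between treatments, 4.99% in their interaction and 15.3% between replicates within groups. Arrays of the same RNA had a median SD of 0.15 over genes, biological replicates of a group 0.27, and the 3 centre means of DMSO 0.36. The SD between biological replicates was above that between technical arrays in 86.1% of genes, and that between centres was above that between biological replicates in 67.9%. Arrays of the same RNA shared a slide, whereas the replicates of every group but DMSO of centre 3 were spread over both slides of their centre. The SD between biological replicates thus also holds array and slide error and does not measure biology alone. By group, the median SD of biological replicates was lowest in centre 3, at 0.15 with B[a]P and with DMSO, and highest in DMSO of centre 2 (0.27).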

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

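The tests in this part were written before their results were seen, except those of the array's signal in centre 1, of the slides of DMSO and B[a]P replicate 3 in centre 2 and of genes called again after a correction, which were chosen afterwards. A difference in the B[a]P effect between centres, by the moderated F-test or by camera, singled out the genes and lists named first. No group had the 4 to 10 samples that a test for outlying samples needs.

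The F-test found 2339 genes with a centre-dependent effect. Each named gene among them is given with the pair of centres that differed most. That pair was centres 1 and 2 (log2 change of centre 1 minus centre 2) for SUN2 (3.50), ETNK2 (2.97), PCDHB9 (2.78), CLUH (2.75), FOXN2 (-2.52), SH2B1 (2.41), ZNF76 (2.31), SDS (2.17), BCL10 (-2.11), GTF2H5 (-1.16), SRP14P1 (-0.96), CDC25B (0.85) and HADHA (0.82). It was centres 2 and 3 (centre 2 minus centre 3) for HSD3B1 (-4.67), C2orf68 (-3.21), DBNDD1 (-2.92), TINAGL1 (-2.73), TGM5 (-2.54), SURF6 (-2.42), SRCAP (-2.32), GPC6 (2.04), LRMDA (2.04), AP1B1 (-1.99), ALDH3A1 (-1.92), PABPC3 (1.90), CDKN1A (-1.65), CARNMT1 (1.44), BTG2 (-1.17), CEBPA (-1.15), LIG3 (-0.99) and CD68 (-0.83).

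For 4 genes the largest difference was between centres 1 and 3 (centre 1 minus centre 3) and did not pass pairwise: AKAP14 (-1.42; adjusted p = 0.294), AKR1C1 (0.94; 0.277), CPS1 (1.05; 0.477) and ELAVL3 (-3.63; 0.442). Of all these genes, AKAP14, CARNMT1, ELAVL3, HSD3B1, PCDHB9 and TGM5 were not well above background in 1 or both groups of at least 1 of the centres compared, so that their differences are fitted values and no measured sizes.

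Histones differed between centres 1 and 2 (camera adjusted p = 7.73e-07), 1 and 3 (0.0283) and 2 and 3 (0.00101; p = 0.0698, 0.338 and 0.191 with an estimated correlation). Metallothioneins differed between centres 1 and 2 (adjusted p = 0.0204; p = 0.264 with an estimated correlation). For p53 targets centre 3 differed from centre 1 (adjusted p = 7.73e-07; p = 0.0519 with an estimated correlation) and centre 2 (3.11e-05; p = 0.088 with an estimated correlation). The B[a]P change of homologous recombination and Fanconi genes was lower in centre 3 than in centre 1 (adjusted p = 0.00348; p = 0.127 with an estimated correlation) and centre 2 (5.03e-04; p = 0.0795 with an estimated correlation). G1/S genes differed likewise (5.95e-10 and 4.83e-05; p = 0.0385 and 0.142 with an estimated correlation), as did mitotic genes (0.0283 and 0.00101; p = 0.31 and 0.168 with an estimated correlation).

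The response seen in centre 2 and not in centres 1 and 3 was weighed first. In centre 2 the bright-corner control spots were dim on the slide of replicate 3 and on B[a]P replicates 1 and 2, and bright on DMSO replicates 1 and 2, so a labelling or hybridisation batch could have added to the change of replicates 1 and 2. Over 5250 genes the excess in replicate 3 was 0.585 ± 0.010 (bootstrap SE over genes) of that in replicates 1 and 2, between the bounds of 0.5 and 0.8 set beforehand. It had the same direction in 80.6% of genes. The genes were chosen on replicates 1 and 2, which can lower the ratio. The same changes of centres 1 and 3 were subtracted on both sides, which can raise the agreement in direction. Neither value is thus an independent check. Against the batch, DMSO replicate 3 lay toward the excess in 51.5% of genes (median 0.022 of it), and the shortfall lay in B[a]P replicate 3 (-0.34); these are single RNAs on another slide, scanned 77 days apart from the first, so the batch stays open. Probe GC content was excluded as the whole cause, since 2301 genes were called after its trend was removed, 1848 of them among the 2339. Quantile normalization left 2340, with 1930 among the 2339, so unequal signal distributions of the arrays were not the whole cause. The excess itself hardly correlated with mean signal (rho = -0.016). Normexp background correction with its offset of 50, however, left 147 centre-dependent genes and no call in centre 2, so a cause that depends on signal level stays open. Each centre kept its own cells, and no test separated a biological cause.

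The weaker B[a]P profile of replicate 2 of centre 1 held 0.291 of the log2 response of the other 2 replicates over 798 genes, where the DMSO replicates held 0.08, -0.154 and 0.075. RNA mixed with untreated RNA would give the same linear share to genes that rose and genes that fell. These shares were 0.151 ± 0.011 and 0.452 ± 0.020 (bootstrap SE over genes; difference 0.301), where a simple mixture predicts equal shares. The genes were chosen in part on the response of the other 2 replicates, against which the shares were also taken. That choice can make the shares unequal even in a mixture. The SE resamples genes of 1 RNA and does not measure the error of that replicate, so a simple mixture stays open. A swap with a DMSO sample was excluded because no DMSO replicate exceeded 0.08, and low signal because the array's 75th percentile was 1169, within the range of the centre. No biological explanation was tested.

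Level differences between centres in DMSO were also weighed. The Feature Extraction version and scanner model were excluded as the whole cause, since centres 2 and 3 shared both and differed in 9102 genes, and probe GC content since 12516 genes differed after its trend was removed, 11021 of them among the 12331. Across genes the differences hardly correlated with GC content (rho = -0.056, 0.011 and 0.002 for centres 1 and 2, 1 and 3, and 2 and 3). They did correlate with mean signal (rho = 0.271, 0.489 and 0.345). The count was 2033 under normexp background correction, 15846 under median scaling and 12485 under quantile normalization. A cause that depends on signal level was therefore not excluded. The labels give each centre its own cell bank, but no test separated cells from slides and handling.

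In other splits of the samples, 1 of 10 splits within each centre, the real one, gave as many genes (1, 2854 and 6473; highest other 0), and 10 splits are too few for a share under 0.05. For the combined effect 1 of 100 drawn splits, the real one, reached 7924 (highest other 3258), and for DMSO 1 of 100 reached 12331 (highest other 5990). For centre dependence 2 of 100 reached 2339. The highest other, 2830, kept the B[a]P and DMSO samples of centres 1 and 2 apart and mixed centre 3. In such a draw the 2 treatments of a centre may also be exchanged as a whole. The draws mixed treatments within centres and so broke up the B[a]P effect itself, and they do not test centre dependence alone.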

How the results depend on the processing

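Normexp background correction, removal of the GC trend, the slide block for the overlap, lists and centre dependence, and omission of a centre for lists and centre dependence were among the tests chosen after the data were seen. Of the values of named genes over all alternatives, 2547 of 2659 in the combined fit, 120 of 130 in centre 2, 128 of 130 in centre 3 and 4 of 13 in centre 1 kept their side of the threshold and, where they passed it, their direction. The same held for 583 of 608 list values. Values that did not pass could change sign and still count as kept. At a minimum of 2-fold, centre 2 had 1880 genes, centre 3 1576, the combined fit 965 and the overlap 0; under an adjusted threshold of 0.01 the counts were 0, 489, 3004, 5037 and 0, which follows from the stricter limit. Quantile normalization left 0 in centre 1 (3306 at an unadjusted p under 0.05) and an overlap of 0, and median scaling gave an SD of DMSO centre means of 0.46. Median scaling turned the majority of calls from falls to rises in centre 2 (51.2% rose), centre 3 (52.7%) and the combined fit (54.8%).

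Normexp background correction on the median signal, the one such column in all files, kept 95 named results, while 55 no longer passed and 5 reversed. It gave 0 genes in centre 1 (1533 unadjusted), 0 in centre 2 (1864), 3268 in centre 3, 2532 combined, 147 centre-dependent, an overlap of 0, 2033 in DMSO, correlations of 0.595, 0.417 and 0.329, and SDs of 0.19 and 0.40 between technical and biological replicates. It turned CYP1B1 (-0.34), KRT13 (-0.25), DIO3OS (-0.021) and ANKRD30BP2 (-0.055 combined, -0.17 in centre 2). This setting added an offset of 50 to the corrected signal, where the median processed signal of the arrays ran from 26.1 to 125.8. The offset was not varied, so its effect cannot be told apart from that of the background correction, and the cause was not tested. Median changes were -0.29, -0.31 and 0.01 in centres 1, 2 and 3 there, against -0.12, 0.06 and -0.09, and 54.6% of genes called in centre 3 rose, against 44.4%.

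Without a filter on dim probes the counts were 0 (3304 unadjusted), 1709 and 4220, the overlap 0 and the correlations 0.276, 0.559 and 0.389. Among genes detected in all 18 replicates centre 1 had 30 genes, the overlap 24, centres 1 and 2 correlated with 0.446 and centres 1 and 3 with 0.738, and the SD of DMSO centre means was 0.30. With every probe on its own centre 2 had 4842 and centre dependence 3811, as more probes than genes were tested. Technical array A alone gave an overlap of 0.

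With the replicate number as a block, centre 1 had 0 genes (3937 unadjusted), centre 2 1322, the overlap was 0, and centre 3 (6732), the combined fit (8362), centre dependence (2287) and lists (10) stayed within 1.5 times. Residual correlations of same-numbered replicates ran from -0.06 to 0.36, and some samples correlated best with another number, so whether the numbers pair the samples is not settled. In centre 2 the number followed the slide, since replicate 3 of both treatments lay on a slide apart from the others. The same held in centre 1 for replicate 1 of both treatments, the pair with the residual correlation of 0.36. The slide as a block gave 0 (3114 unadjusted), 5215 and 2448 with an overlap of 0, and tests within slides 0 (884), 9052 and 2767. The spread of all 18 replicates gave 654, 7174, 3304 and an overlap of 365. Without centre 2 no gene was centre-dependent (0; 1927 unadjusted), without centre 3 821 were, and 4413 changed in the combined fit. With an estimated correlation 0 lists were called in the combined fit. The causes were not tested.

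Leaving out each replicate in turn gave 0 to 686 genes in centre 1, 323 to 5098 in centre 2, 3557 to 6495 in centre 3, 6838 to 9121 combined, 1370 to 3733 centre-dependent, an overlap of 0 to 231, 10294 to 13498 in DMSO, 9 to 11 lists, and correlations of 0.315 to 0.479, 0.556 to 0.762 and 0.407 to 0.467. An alternative with array weights did not converge and was removed after its counts had been seen. The planned normexp on the mean signal was not run, since 2 centres lack that column. Between 61.9% and 77.2% of probes were well above background, which limits what can be read from dim genes.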

Other observations

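The tests of probe distance in this part, other than the regression, were written after the values had been seen. Genes of fatty acid oxidation and PPARA targets, which burn and store lipid, moved in both directions with B[a]P: 5 of 20 rose and 5 fell, also adjusted over the list alone (limma combined fit; camera adjusted p = 0.874), with a median of -0.05 and a mean of 0.02. CPT1A, which admits fatty acids to mitochondria, rose by 1.58 ± 0.13, while the receptor PPARA (-0.67 ± 0.11) and the trifunctional protein subunit HADHA (-0.44 ± 0.08) fell; of the dimmer probes, 2 of PPARA (0.22 ± 0.15 and -0.18 ± 0.09) and that of HADHA (adjusted p = 0.845) did not pass, and 1 of PPARA fell (-0.49 ± 0.17). Chosen after their values were seen, the lipid droplet protein PLIN2 (0.70), ACADVL (0.29) and HADHB (0.26) rose, and FABP1 (-0.54) and EHHADH (-0.32) fell.

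Of 15 genes of drug metabolism under PXR and CAR, 3 rose, CYP3A7 (0.90 ± 0.21), the export pump ABCB1 (0.74 ± 0.11) and ALAS1 (0.29), and 3 fell, CYP2E1 (-0.83 ± 0.14), the transferase GSTA2 (-0.52 ± 0.10) and POR (-0.25); adjusted over the list alone 3 rose and 4 fell (camera adjusted p = 0.603). Of 22 ATF4 and unfolded protein response genes, 3 rose and 5 fell, also over the list alone (camera adjusted p = 0.666), though the list shifted down with every probe on its own at the preset correlation (adjusted p = 0.0494; for the list as first tested, adjusted p = 0.706 with an estimated correlation). The stress factor ATF3 rose by 1.32 ± 0.19, with DDIT3 (0.36) and DNAJB9 (0.35), whereas the serine synthesis enzyme PHGDH (-1.01 ± 0.11), the chaperone HSPA5 (-0.43 ± 0.10), XBP1 (-0.41 ± 0.11), SHMT2 (-0.30) and PSAT1 (-0.24) fell. ALAS1, POR, DDIT3, DNAJB9, SHMT2 and PSAT1 were chosen after their values were seen.

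Fibroblast, endothelial, and squamous or lung markers did not shift as groups in the combined fit. Fibroblast markers did shift down in centre 1 on its own 6 replicates (camera adjusted p = 0.0377; in the fit of all 18, adjusted p = 0.229 with an estimated correlation). Of 5 fibroblast markers COL1A1 (-1.02 ± 0.17) and PDGFRB (-0.55 ± 0.14) fell, and THY1 (-0.38 ± 0.20) and COL6A3 (-0.29 ± 0.17) did not pass (2 fell over the list alone; camera adjusted p = 0.138). COL1A1 was below background in both groups of centre 1 and with B[a]P in centre 2, so that its combined change is a fitted value and no measured size; the same holds for CYP2E1, below background with DMSO in centre 1 and with B[a]P in centre 2. Of 4 endothelial markers PECAM1 fell (-0.80 ± 0.14; 1 over the list alone; camera adjusted p = 0.476), and CLDN5, VWF and ENG did not pass. Of 6 squamous and lung markers KRT13 rose (0.84 ± 0.27; 1 over the list alone; camera adjusted p = 0.952) but turned to -0.25 under normexp background correction, and KRT14, SFTPC and SCGB1A1 did not pass. A dimmer probe of KRT14 was called higher (1.47 ± 0.27) and one of SFTPC lower (-0.67 ± 0.13).

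Adducts of B[a]P on DNA can stall transcription, so long genes might fall more than short ones. With the distance between a gene's outermost probes as a stand-in for its length, 296 genes with probes at least 100 kb apart were set against 4688 within 10 kb. The medians of the combined change differed by -0.038 (p = 0.212 with an estimated correlation), which leaves the idea open. In centre 3 the medians were -0.21 and -0.02 (p = 0.00221 with an estimated correlation), and 30.7% against 12.5% of the genes fell. Centres 1 and 2 did not pass (camera p = 0.577 and 0.579 with an estimated correlation). The medians there were -0.078 and -0.070 in centre 1. In centre 2 the genes with far probes had the higher median (0.172 against 0.082), and 7.77% against 6.85% fell. After regression on probe GC content and signal level 103% of the combined mean difference was left, which decides nothing where no shift passed; in centre 3 96.5% was left.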
